A study of Drosophila melanogaster with 6 samples.

How the data were processed

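The study hybridised RNA of methotrexate-treated and untreated Drosophila melanogaster material to 2-colour spotted cDNA arrays: 4 arrays of S3 cells and 2 of ovaries, on 2 array designs. The deposited values are log ratios of the 2 channels of each array, taken here as log2. The base is not stated in the sources used here; as a natural log the widest value, -11.97, would be a ratio of 1.58e+05, wider than array scanners usually record. How the authors corrected background, normalised and chose the numerator of the deposited log2 ratios is not given in the sources used here. Array medians as deposited were 0.08, -0.02, 0.06 and 0.18 for S3 arrays 1 to 4 and 0.11 and 0.06 for ovary arrays 1 and 2, so scale and direction stay unknown and centring is near but not at 0. Signal over background is not in the values analysed.

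Per the labels, the treated S3 RNA carried Cy3 on arrays 1, 3 and 4 and Cy5 on array 2. The treated ovary RNA carried Cy5 on both arrays, in channel 1 on array 1 and in channel 2 on array 2, although the series text says that dyes were swapped. By a rule set before the data were examined, array 2 of a group was turned where its mean correlation with the group's other arrays was below 0. That mean was -0.0230 for S3, so S3 array 2 was turned, and 0.753 for ovary, which was left as deposited. At a mean so near 0, the direction of S3 array 2 is not settled, nor is it with print blocks centred (mean 0.0997).

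Spots were named through the platform annotation, with symbols updated by Entrez gene number to those of Release 6 of the Drosophila genome. On the S3 design 15116 spots had 1 gene, 102 had several and 12430 had none; on the ovary design the numbers were 5666, 152 and 11078. Of the 6795 S3 genes 6692 had a current symbol, as did all 2377 ovary genes. Spots with no or several genes were tested as spots and not named. No genomic positions are given, because no genome build belongs to these values. Spots of 1 gene were averaged per array after centring, and genes with a value on every array of the group were tested (6764 for S3, 2377 for ovary). Of genes with more than 1 pair of neighbouring spots, 340 of 686 on the S3 design and 116 of 288 on the ovary design had pairs with mean ratios of opposite sign. Among the 63 such ovary genes that passed, 1 did.

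Each array was centred on its median and the mean log2 ratio of each gene was tested against 0, two-sided, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. S3 and ovary were fitted apart, and together, with a mean per group, for genes that differ between them. Gene lists written before the data were examined were tested with camera (preset correlation 0.01, at least 5 measured members, adjusted over lists), and with an estimated correlation and fry beside it. One older identifier written in the purine list now names COX7A, which is also a member of the oxidative phosphorylation list. It was kept because the lists were fixed. COX7A thus counts among the 9 purine members on the S3 arrays, on the negative side with blocks centred (-0.163). Files were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

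The genes named are, per group and side, the 12 with the largest mean among those that passed with the same sign on every array. Where fewer passed, the list was filled up to 8 by the largest moderated t among genes with the same sign on every array, which then did not pass. Further genes named are up to 4 members of each list with the smallest p, and Ts always. Members are printed for some of the lists only. The same rule was applied to the S3 values after centring of print blocks.

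The layout of print blocks is not stated and was read from the period of the values along the rows: 48 blocks of 576 spots on the S3 design, and 32 blocks of 528 spots, in 22 rows of 24, on the ovary design. Centring on print blocks, or on blocks and rows within blocks, was added after these patterns were seen. Other alternatives were set beforehand: no centring, equal scale between arrays, spots in place of genes, robust eBayes, the other sign of array 2, a threshold of 0.10, a 1.5-fold rule with no test, leaving out genes whose duplicates disagree, a dye term, genes on at least 3 of 4 S3 arrays, a joint fit for ovary, and each array left out in turn. Equal scale was set with the limma function for median absolute values, which is what the planned function applies to ratios.

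The gene test was tested on simulated data with the spread of each group. For S3 (6764 genes, 4 arrays) it recovered 75% of 100 genes changed 2-fold and 100% of 100 changed 4-fold, with 12 false calls. For ovary (2377 genes, 2 arrays) it recovered 81% and 100%, with 9 false calls. In simulated S3 values camera called a P450 list shifted by 0.30 and 0 of the other lists. These results hold for the simulated values only and are no estimate of recovery on the real arrays. The real arrays also carry print patterns, and the sign of S3 array 2 is not settled. For ovary, limma's prior set the same spread for every gene, and whether real genes share it was not tested.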

Results

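Gene expression under methotrexate, an antifolate drug, was measured on 2-colour spotted cDNA arrays in Drosophila S3 cells, a cultured cell line, and in fly ovaries. S3 cells were given the drug at 5.2e-08 M for 4 days (4 arrays), and flies were given 5 ppm for 5 days before their ovaries were taken (2 arrays). Each array compared treated with untreated RNA of the same material. The S3 arrays carried 27648 spots, of which 15116 were assigned to 1 gene each (6795 genes), and the ovary arrays, of another design, carried 16896 spots, of which 5666 were assigned to 1 gene each (2377 genes). The number of arrays limits the precision of every value. The labels do not say that the RNA came from separate cultures or flies, so each p-value measures only the spread between arrays, which may be technical.

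Neither the labels nor the values settle which channel was the numerator of the deposited ratios, so all log2 ratios are given as positive or negative with no direction relative to methotrexate. The logarithm's base is not stated either and was taken as 2. Neighbouring duplicate spots correlated at r = 0.288, 0.325, 0.252 and 0.474 on S3 arrays 1 to 4, and at 0.910 and 0.839 on ovary arrays 1 and 2. Across genes, which are not independent replicates, the ovary arrays correlated at r = 0.753. S3 arrays 1 and 2 correlated at r = -0.187, and the other S3 pairs lay between -0.0798 and 0.206. The medians of the 48 print blocks of an S3 array ran across the slide in opposite directions on arrays 1 and 2 (r = -0.915 between their block medians). Neighbouring duplicates share a block, and with print blocks centred they correlated at only r = 0.157, 0.165, 0.220 and 0.455 on S3 arrays 1 to 4. On ovary arrays 1 and 2 the values were then 0.908 and 0.820.

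**Figure D1:**
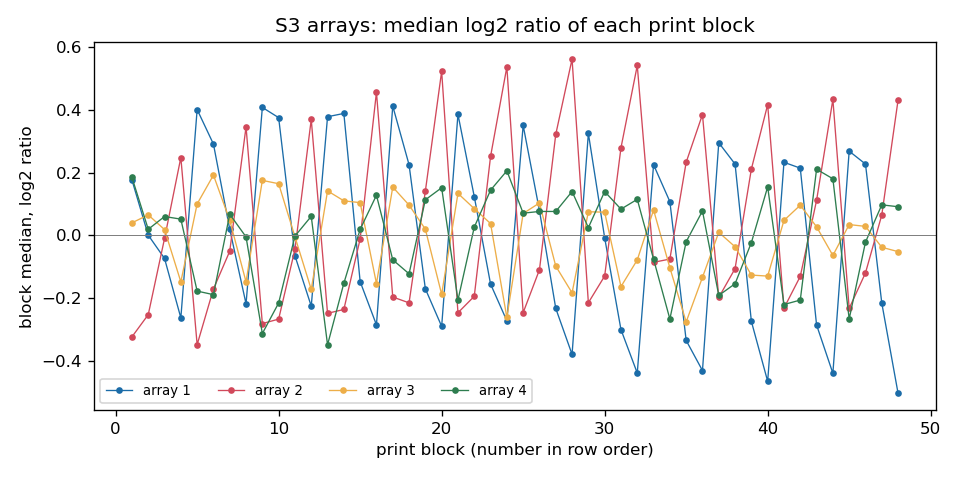
Median log2 ratio (y axis) of each of the 48 print blocks (x axis) of the 4 S3 arrays, 1 line per array, after centring each array on its median. Array 1 ranged from -0.50 to 0.41 and array 2 from -0.35 to 0.56, and peaks of array 1 fall where array 2 has troughs.

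The S3 comparison asked which genes differed between treated and untreated cells. No gene passed in the S3 cells when each array was centred on its median and array 2 was turned by its mean correlation with the others: limma gave 0 of 6764 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 505 genes, against 338.2 by chance for arrays with no print gradient. As deposited, block medians of arrays 1 and 3 correlated at r = 0.788, and both ran against array 2 (-0.915 and -0.83). Turning array 2 lines up these gradients, so the excess over 338.2 cannot be credited to genes. The mean correlation of array 2 with the others was only 0.0230 once it was turned. As deposited array 2 correlated with array 4 at r = 0.198, so that turning sets these arrays against each other. The negative side was led by CG11426, at a mean log2 ratio of -1.39 ± 0.36 (SD, n = 4), negative on 4 of 4 arrays, with a limma adjusted p of 0.395. It was followed by png, a regulator of translation at egg activation, at -1.06 ± 0.24 (SD, n = 4), and by the RNA helicase gene Dbp73D at -1.65 ± 0.94 (SD, n = 4). On the positive side stood HSPBAP1 at 0.87 ± 0.28 (SD, n = 4), the mitochondrial ribosomal protein gene mRpL15 at 0.87 ± 0.64 (SD, n = 4) and CG31912 at 0.67 ± 0.05 (SD, n = 4). With the sign of array 2 left as deposited, 3 genes passed, all negative: CG15347 at -2.21, fat-spondin at -1.73 and CG16959 at -1.50, each with a limma adjusted p of 0.0318. These are the same arrays under another reading of 1 sign, and the sign is not known.

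Once each print block was centred on its own median, a step added after the gradients had been seen, all 6 pairs of S3 arrays correlated above 0 as deposited (r from 0.0605 to 0.180), and array 2 was not turned. The 6 genes named above had been chosen for the same sign on every array with array 2 turned. Leaving array 2 unturned therefore brings their means nearer 0 by itself, apart from any effect of block centring. With blocks centred and array 2 as deposited, CG11426 was at -0.55, png at -0.42, Dbp73D at -0.67, HSPBAP1 at 0.44, mRpL15 at 0.51 and CG31912 at 0.33, with limma adjusted p of 0.610 or more. In that reading fat-spondin, an extracellular matrix gene, had a mean log2 ratio of -1.73 ± 0.41 (SD, n = 4), CG16959 of -1.50 ± 0.29 and the sterol-binding protein gene Npc2a of -1.49 ± 0.33. Each was negative on 4 of 4 arrays with a limma adjusted p of 0.0537, short of 0.05. The lipase gene Lip4 followed at -1.57 ± 0.52, then Ance, an angiotensin-converting enzyme homologue, at -1.15 ± 0.14, CG16743 at -1.20 ± 0.20, Gs1, a glutamine synthetase gene, at -1.18 ± 0.27 and CG15347 at -2.26 ± 0.99 (SD, n = 4 each), with limma adjusted p of 0.0716 or 0.0720. The positive side did not come as near: the heat-inducible chaperone gene Hsp68 was at 1.09 ± 0.54 (limma adjusted p = 0.186, positive on 4 of 4 arrays), Fife at 1.03 ± 0.54, the amino acid transporter gene mnd at 0.90 ± 0.50, CG4983 at 0.87 ± 0.47, the insulin-binding protein gene ImpL2 at 1.01 ± 0.77 (limma adjusted p = 0.401), comr at 0.70 ± 0.26, tobi at 0.65 ± 0.28 and the initiation factor gene eIF2beta at 0.59 ± 0.19 (SD, n = 4 each). limma gave 0 of 6764 genes at an adjusted p under 0.05, 9 at under 0.10, all negative, and 644 at an unadjusted p under 0.05. Leaving out 1 array raised the adjusted p of fat-spondin to as much as 0.331 and that of Npc2a to as much as 0.373.

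**Figure D2:**
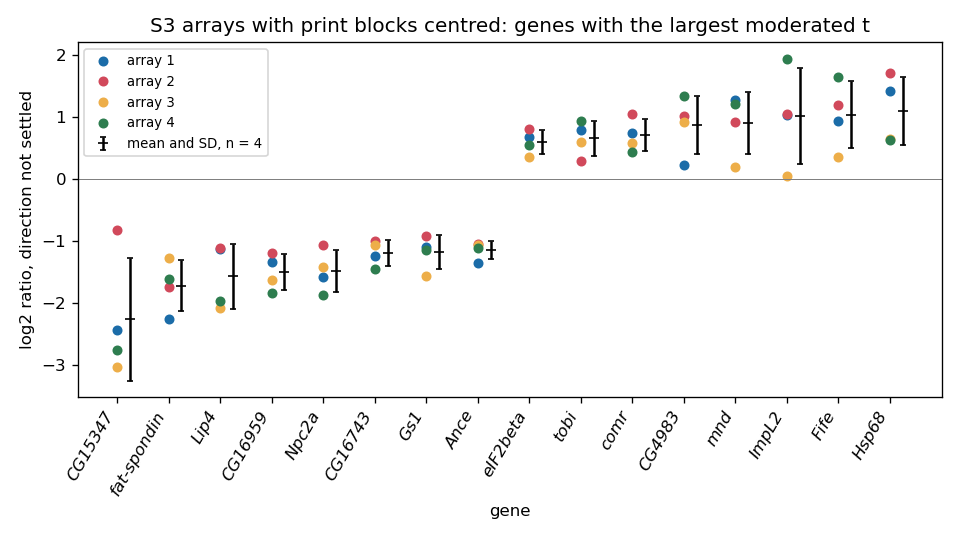
Log2 ratio (y axis) of 16 genes (x axis) on the 4 S3 arrays after centring of print blocks, 1 point per array, with the mean and SD (n = 4) beside them. The genes are the 8 with the largest moderated t on each side; none passed an adjusted p of 0.05, and CG15347 has the widest spread on the negative side (SD 0.99).

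Of the gene lists fixed before the data were examined, 25 had at least 5 members on the S3 arrays. The cytochrome P450 genes, enzymes of detoxification and hormone synthesis, leaned to the negative side: 50 of 63 members were negative with blocks centred, at a median of -0.20, and camera gave an adjusted p of 4.69e-04. That call was lost at an adjusted p = 0.456 with an estimated correlation. No single P450 gene passed over all genes, and 0 passed when adjusted over the list alone. The members with the smallest p were Cyp6a8 at -0.78 ± 0.35, Cyp12a4 at -0.65 ± 0.09, Cyp9f2 at -0.57 ± 0.17 and Cyp12e1 at -0.74 ± 0.51 (SD, n = 4 each), all negative on 4 of 4 arrays. With arrays centred on their medians and array 2 turned, 44 of 63 were negative, at a median of -0.15, and camera's adjusted p was 0.202. The call changed with the sign of array 2, which is not settled. With array medians and array 2 as deposited it stood (camera adjusted p = 6.13e-04), and with blocks centred and array 2 turned camera called 0 lists. With array 2 left out, the call stood under both centrings (camera adjusted p = 0.00449 with array medians and 0.00170 with blocks centred). Without replicate 3 the P450 call with blocks centred was lost, at an adjusted p of 0.0732.

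Genes of hemocytes, the blood cells of the fly, and of the extracellular matrix were negative for 14 of 21 members with blocks centred (median -0.18, camera adjusted p = 0.0383), again with an adjusted p = 0.456 with an estimated correlation. The list also passed with fry (adjusted p = 0.0190), which the P450 and translation lists did not (0.181 and 0.0628). None of its members passed over all genes and 4 passed on the negative side when adjusted over the list alone: Ance, the scavenger receptor gene crq at -0.95 ± 0.19, Glt at -1.04 ± 0.34 and Nplp2 at -0.96 ± 0.72 (SD, n = 4 each). Translation factors and tRNA synthetases were positive for 13 of 18 members (median 0.16, camera adjusted p = 0.0383, adjusted p = 0.456 with an estimated correlation), with 0 past over all genes and 0 adjusted over the list alone. The estimated correlation was 0.0334 for the P450 list, -0.0337 for the hemocyte list and -0.0149 for the translation list. For the hemocyte and translation lists it lay below the preset 0.01, so correlation between members does not account for the lost calls. With an estimated correlation, camera rests on the few degrees of freedom between the arrays. Besides eIF2beta, this list was led by eIF3c at 0.54 ± 0.40, IleRS at 0.40 ± 0.17 and eIF4A at 0.55 ± 0.65 (SD, n = 4 each), of which eIF3c was at -0.01 on array 1. With array medians and array 2 turned, camera called 0 of the 25 lists with the preset or an estimated correlation, and fry called 0. The medians of both these lists then lay near 0 (0.00 and 0.04). The hemocyte list lost its call without any 1 of the 4 arrays (adjusted p from 0.0568 to 0.177), and the translation list lost it without replicate 2, 3 or 4 (adjusted p up to 0.186) and with a dye term (0.0553).

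**Figure D3:**
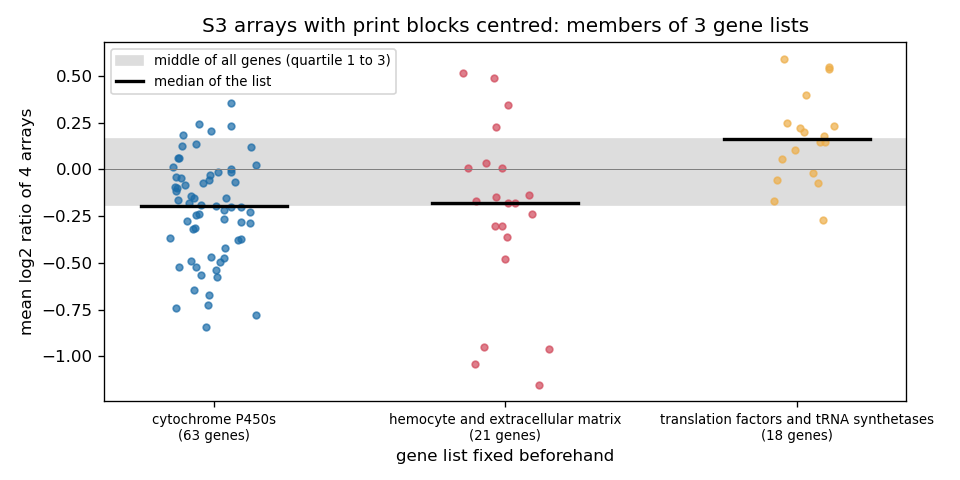
Mean log2 ratio over the 4 S3 arrays with print blocks centred (y axis) of each member of 3 gene lists (x axis), 1 point per gene, with a bar at each list's median and a grey band over the middle quartiles of all genes. The medians are -0.20 for 63 P450 genes, -0.18 for 21 hemocyte and matrix genes and 0.16 for 18 translation genes.

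The pathways that methotrexate acts on did not pass as groups in S3 cells. With blocks centred, folate and one-carbon metabolism had 9 of 15 members negative (median -0.07, camera adjusted p = 0.507), purine synthesis 5 of 9 (median -0.05, 0.704) and pyrimidine and deoxynucleotide synthesis 5 of 10 (median 0.01, 0.923), with 0 members past the gene test, also adjusted over the list alone. Ts, the thymidylate synthase gene, had values of 0.08, 0.37, 0.68 and -1.21 on arrays 1 to 4, a mean of -0.02 ± 0.83 (SD, n = 4). Fpgs1, which encodes a folylpolyglutamate synthase, was at -0.40 ± 0.16 and negative on 4 of 4 arrays (limma adjusted p = 0.509), and the methyltransferase gene Bhmt was at -0.88 ± 0.65 (SD, n = 4). DNA replication genes were negative for 17 of 26 members (median -0.14, camera adjusted p = 0.343), among them the single-strand binding protein gene RPA1 at -0.63 ± 0.24 and the origin recognition gene Orc5 at -0.95 ± 0.64 (SD, n = 4 each). Genes of the cell cycle and mitosis (14 of 24 negative, camera adjusted p = 0.923) and of the DNA damage response (13 of 26 negative, 0.753) were spread over both sides. The cell cycle list had a median of -0.03 while the test pointed to the positive side. None of these lists passed with array medians and array 2 turned either.

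The ovary comparison asked the same of treated and untreated flies, and here many genes stood apart from the spread between the arrays. limma called 926 of 2377 genes (39.0%) at an adjusted p under 0.05, 497 positive and 429 negative. By the labels the treated RNA carried Cy5 on both ovary arrays. In these calls, and in the ovary genes and lists below, a gene's dye effect therefore cannot be told apart from a treatment effect. The largest positive ratio was that of kra, a translation regulator, at a mean log2 ratio of 2.42 ± 0.55 (SD, n = 2; limma adjusted p = 8.60e-15, positive on 2 of 2 arrays). After it came Vajk3 at 2.02 ± 0.48, the ceramide kinase gene Cerk at 1.98 ± 0.28, the chromatin gene simj at 1.98 ± 0.30, CG9853 at 1.98 ± 0.51, Mink at 1.94 ± 0.33 and heph, which encodes an RNA-binding protein, at 1.88 ± 0.31 (SD, n = 2 each). The others of the 12 were rig, CG7101, the tensin gene by, the transcription factor subunit gene Tfb1 and Atxn7, down to a mean of 1.81.

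On the negative side, TrissinR, a neuropeptide receptor gene, was at -1.84 ± 0.58 (SD, n = 2; limma adjusted p = 8.86e-09, negative on 2 of 2 arrays). CG32119 was at -1.71 ± 0.04, the kinase gene Mekk1 at -1.65 ± 0.92, the transcription factor gene odd at -1.57 ± 0.86, the zinc finger gene woc at -1.54 ± 1.23 and amos, a proneural transcription factor gene, at -1.53 ± 0.14 (SD, n = 2 each). IFT46, CG1698, Hsp68 at -1.36 ± 0.80, COX6AL, BckdhA and pippin completed the 12, up to -1.29. The 2 values of woc differed most among these, at -0.66 and -2.41.

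**Figure D4:**
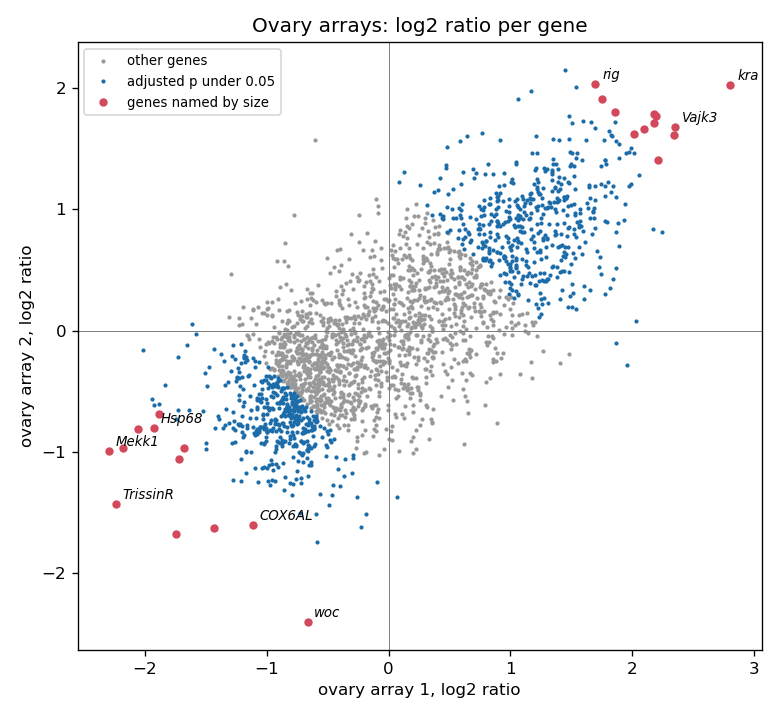
Log2 ratio per gene on ovary array 1 (x axis) and ovary array 2 (y axis), 1 point per gene for 2377 genes, with those at an adjusted p under 0.05 in blue and the 24 named by size in red. The points follow a rising diagonal (r = 0.753), and kra lies farthest out at 2.81 and 2.03.

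Ovary ratios also followed the row of the print block in which a spot lay. Rows explained 20.8% of the variance between spots on array 1 and 15.9% on array 2, and the medians of the 22 rows correlated at r = 0.935 between the arrays. After centring on print blocks and rows, a step added after seeing this, limma called 780 genes (431 positive, 349 negative), and 504 of the 926 genes (54.4%) were called on the same side as before. All 12 positive genes named above and 11 of the 12 negative ones were among these, and Hsp68 was not (-0.53, limma adjusted p = 0.0704). Apart from kra (2.57), CG1698 (-1.68) and pippin (-1.36), the means of all 24 moved toward 0, among them those of amos (-0.76), CG32119 (-0.99), TrissinR (-1.08), odd (-0.98) and Mink (1.24). Without centring of the arrays, the split of the calls moved to 559 positive and 284 negative. With array 2 turned, 0 genes passed. In a joint fit with the S3 arrays, 306 genes passed with both ovary arrays, 0 without replicate 1 and 1 (kra) without replicate 2. The 2 arrays leave 1 residual degree of freedom, and limma's prior set the spread of every gene to the same value.

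**Figure D5:**
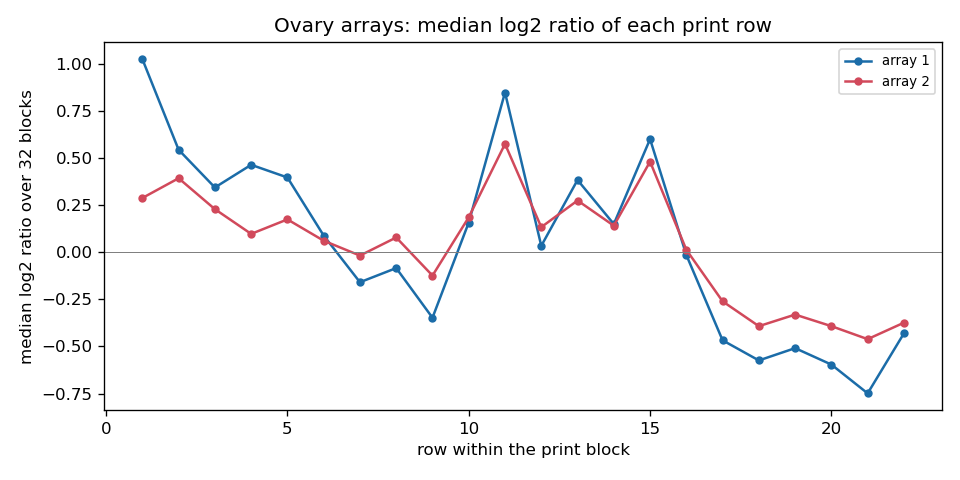
Median log2 ratio over the 32 print blocks (y axis) of each of the 22 rows within a block (x axis), 1 line per ovary array. Array 1 ranged from -0.75 to 1.02 and array 2 from -0.46 to 0.57, and the lines rise and fall together.

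Of the fixed lists, 15 had at least 5 members on the ovary arrays, and camera called 0 of them with the preset correlation. An estimated correlation and fry also gave 0 calls. With 1 residual degree of freedom these other tests could hardly call any list, so their 0 adds nothing to that of camera with the preset. The smallest camera adjusted p was 0.495. Of all ovary genes 39.0% passed, and 32.8% with blocks and rows centred. The counts of list members that passed, here and below, are to be read against these shares and are no result about a list. DNA damage genes had 0 members past on the positive side, 2 past on the negative side and 9 not past, also adjusted over the list alone: the repair nuclease gene mei-9 at -0.87 ± 0.64 and tefu, the fly ATM gene, at -0.84 ± 0.63 (SD, n = 2 each), of which tefu did not pass after row centring (limma adjusted p = 0.243). p53 at -0.77 and Tdg at 0.76 passed only then (limma adjusted p of 0.00542 and 0.00621). Of 5 cell cycle genes, 3 passed on the positive side and 1 on the negative side, also adjusted over the list alone. They were the condensin gene glu at 0.83 ± 0.42, the cohesin gene SMC1 at 0.75 ± 0.38, the retinoblastoma homologue Rbf at 0.74 ± 0.50 and barr at -0.73 ± 0.32 (SD, n = 2 each). glu, SMC1 and barr did not pass after row centring (limma adjusted p of 0.957, 0.781 and 0.778). Of 3 replication genes, that of the largest subunit of chromatin assembly factor passed at 0.96 ± 0.21 (SD, n = 2; limma adjusted p = 0.00316). The helicase gene RecQ4 did not pass at -0.58 (limma adjusted p = 0.0754), but did after row centring at -0.85 (0.00192).

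The folate list had 3 members on the ovary arrays and none passed, also adjusted over the list alone. Ts was at 0.52 and -0.40 on the 2 arrays, a mean of 0.06 ± 0.65 (SD, n = 2; limma adjusted p = 0.869). Of 3 purine genes, the adenylate kinase gene Adk3 passed at 0.77 ± 0.32 (SD, n = 2; limma adjusted p = 0.0186) but not after row centring (0.262), where Adsl passed instead at -0.61 (0.0336). Both pyrimidine genes, Ts and CG3788, did not pass; after row centring Ts passed only when adjusted over the list alone, with values of opposite sign on the arrays (1.24 and -0.18). Heat shock genes and chaperones had 2 members past on each side of 9, also adjusted over the list alone: Droj2 at 1.72 ± 0.35 and Gp93 at 0.77 ± 0.41 were positive, Hsp68 and Hsc70-1 (-0.69 ± 0.32) negative (SD, n = 2 each). Gp93, Hsp68 and Hsc70-1 did not pass after row centring (limma adjusted p of 0.165, 0.0704 and 0.627), while CCT1 then did, at 0.87 (0.00150). Of 11 germline genes, 3 passed on the positive side and 4 on the negative side, also adjusted over the list alone. Among them were the piRNA pathway gene zuc at 1.27 ± 0.60, Fs(2)Ket at 0.86 ± 0.21, tai at -1.24 ± 0.37 and the sex determination gene Sxl at -1.07 ± 0.09 (SD, n = 2 each). After row centring 2 germline genes passed on the positive side and 1 on the negative side: zuc and Sxl no longer passed (limma adjusted p of 0.161 and 0.350), while cher did, at 0.62 (0.0288).

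Across the 1815 genes measured on both designs, mean S3 and ovary ratios were nearly unrelated. The Spearman correlation was -0.0366 (0.0366 with the ovary sign turned), while single pairs of an S3 and an ovary array lay between -0.105 and 0.0574. The S3 arrays agreed little with each other (mean r = 0.0669 with array 2 turned, against 0.753 for ovary), which by itself limits such a correlation. Dose, exposure and material all differed between the groups. A joint limma fit found 164 genes whose S3 and ovary ratios differed at an adjusted p under 0.05, and 97 with the ovary sign turned. Only 38 genes differed under both signs, and all 38 were among the ovary calls. To differ under both signs, the S3 and ovary ratios of a gene must differ in size. Since no S3 gene had passed, this overlap is largely built in and is no separate evidence of a difference between the materials. kra was the clearest, with a mean of 0.18 on the S3 arrays (n = 4) against 2.42 on the ovary arrays (n = 2), limma adjusted p = 0.00740 (0.00651 with the ovary sign turned).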

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

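The measures below follow rules set beforehand, and the print-block and print-row centring that some of them use was chosen after the data had been seen.

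Of 96 sets of 4 S3 values checked for a lone value (named genes and array measures), 9 had a gap that took up most of the range. Chance gives about 4.8 for independent sets not selected on their values. These genes were named from the same values, and some enter under both centrings, so 9 cannot be read as an excess over chance. With arrays centred on medians and array 2 turned, the gap as a share of the range was 0.881 for Cdc45 (0.16 on array 3, the others -0.83 to -0.71), 0.906 for Sardh (1.05 on array 2) and 0.977 for su(r) (-0.43 on array 1). With print blocks centred it was 0.853 for CycD (0.87 on array 4), 0.888 for p53 (-0.93 on array 4), 0.861 for CG10621 (0.42 on array 4), 0.862 for CG8665 (-0.79 on array 1) and 0.867 for eIF4A (1.51 on array 4, the others 0.12 to 0.31). Among array measures, the share of variance between print rows stood apart on array 4, at 1.42% (0.876).

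S3 and ovary ratios differed in the joint limma fit under both signs of the ovary ratio for 38 genes, and for 41 after print centring. Of the genes named in the report, S3 minus ovary was -2.24 for kra, -2.45 for Cerk, -2.17 for by, -2.13 for CG9853, -2.12 for CG7101, -1.88 for Vajk3, -1.78 for Atxn7 and -1.71 for Mink. It was 1.95 for TrissinR, 1.71 for amos, 1.69 for CG32119, 1.43 for CG1698 and 1.39 for odd. These values take the ovary sign as deposited. With the ovary sign turned some sizes grew, as for kra (2.60) and Mink (2.18), and others shrank, as for Cerk (1.51) and by (1.49). After print centring, kra (-2.42), CG9853 (-1.58), CG7101 (-1.43), Vajk3 (-1.39), Mink (-1.18), Atxn7 (-1.14) and CG1698 (1.64) differed under both signs (values with the ovary sign as deposited).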

How the results depend on the processing

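Print-block and print-row centring were added after seeing the data, and the other settings were planned. No paired analysis was possible because the replicate numbers that S3 and ovary share name different materials on different array designs, and each array already pairs treated with untreated RNA. The S3 count of 0 stayed 0 under every setting but 3: it was 3 with array 2 as deposited, 228 (75 positive, 153 negative) by the 1.5-fold rule with no test, and 0 to 1 leaving out 1 array, the gene being CG15347 without replicate 2. With print blocks centred it was 9 at a threshold of 0.10, 213 by the 1.5-fold rule, 1 with a dye term (CG12115, named after its value was seen) and 0 to 1 leaving out 1 array (CG15347 without replicate 2). The ovary count of 926 was 5040 over spots, because more units were tested, 0 with array 2 turned, and 306 (219 positive, 87 negative) in the joint fit of genes on both designs, among which 697 had passed. Leaving out 1 ovary array in that fit, where the lone array is assumed to vary like the others, gave 0 to 1 (kra without replicate 2). The other ovary settings gave between 780 and 1205. S3 lists called, 0 as reported, were 1 with array 2 as deposited (P450s), 3 with print blocks centred and 0 to 2 leaving out 1 array: P450s and ribosomal proteins without replicate 1, P450s without replicate 2. The 3 lists called with blocks centred became 0 with an estimated correlation, 0 with array 2 turned, 2 with a dye term (translation genes lost, adjusted p = 0.0553) and 0 to 2 leaving out 1 array, down to 0 without replicate 3. The ovary list count was 0 throughout, which says little for fry and the estimated correlation at 1 residual degree of freedom. The Spearman correlation between S3 and ovary, -0.0366, was 0.0366 with the ovary sign turned and 0.0250 after print centring. Genes that differ, 164, were 97 with the ovary sign turned. Agreement between the ovary arrays was 0.734 by the Spearman correlation, 0.693 over spots and 0.814 with blocks centred. For shifts not explained here, the cause was not tested.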

Other observations

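The tests of print blocks, print rows and dye effects, and the sign patterns, were chosen after the correlations between arrays had been seen.

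Immune genes in S3 cells were split between the sides with print blocks centred, 9 of 17 negative. fry gave an adjusted p of 0.00138 for the list, and camera did not call it (adjusted p = 0.296; adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone, 2 passed on the negative side and 0 over all genes. They were spz, which encodes the ligand of the Toll receptor, at -1.28 ± 0.37, and the antifungal peptide gene Drs at -1.41 ± 0.71 (SD, n = 4 each). Muscle genes were negative for 10 of 12 (median -0.18, fry adjusted p = 0.00345, camera 0.234; adjusted p = 0.586 with an estimated correlation), with 0 past, also adjusted over the list alone.

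In the ovary, where 39.0% of all genes passed, redox genes had 1 member past on the positive side, the thioredoxin gene Trx2 at 0.90 ± 0.01, and 3 on the negative side of 10, also adjusted over the list alone: GstZ2 at -0.97 ± 0.16, Prx3 at -0.88 ± 0.04 and Sod2 at -0.78 ± 0.46 (SD, n = 2 each). Sod2 did not pass after row centring (limma adjusted p = 0.952), while Keap1 then did, at -0.63 (0.0274). Of 4 P450 genes, Cyp6u1 at 1.71 ± 0.34 and Cyp12d1-p passed on the positive side and Cyp4ac1 at -0.67 ± 0.28 on the negative side (SD, n = 2 each), also adjusted over the list alone, and all 3 passed after row centring. The early embryonic linker histone gene BigH1 passed at 1.15 ± 0.54 (SD, n = 2; limma adjusted p = 3.69e-04). Of the 11230 ovary spots with no or several genes assigned, 3387 (30.2%) passed when spots were tested, 2297 positive and 1090 negative, against 29.2% of the spots of 1 gene.

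S3 arrays 1 and 2 ran against each other across genes (r = -0.187). The block medians of these arrays correlated at -0.915, and after block centring the gene correlation was 0.0954. Opposite gradients across the print blocks may therefore account for the negative sign.

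With print blocks centred, the S3 arrays correlated above 0 with array 2 as deposited. Rows within blocks do not account for it, since the mean correlation stayed at 0.110 after row centring. Nor does a dye effect of equal size for a gene on both designs: the larger covariance with an ovary array was 0.187 of the mean covariance between S3 arrays (95% bootstrap interval over genes 0.0401 to 0.605), where it predicts 1. A dye effect particular to the S3 hybridizations cannot be told apart from a treatment effect, because the numerator is not known: arrays 1, 3 and 4 correlated more with each other than with array 2 by only 0.0308. An effect of methotrexate stays open and untested.

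The ovary arrays correlated at r = 0.753. Print rows and blocks shared by both arrays are not the whole of it, since r was 0.758 after both were centred, although 45.6% of the calls ended. A dye effect of equal size on both designs predicts a covariance ratio of 1, and it was 0.0171 (95% bootstrap interval 0.00343 to 0.0497). That ratio could hardly reach 1, because the centred S3 means spread less across genes (SD 0.293) than the ovary means (SD 0.585). It speaks only against an equal size, and a dye effect that was smaller on the S3 arrays stays open. A dye effect particular to the ovary hybridizations cannot be told apart from a treatment effect, since 0 ovary arrays were labelled with the treated RNA in Cy3. Methotrexate stays open as well, so the 926 ovary calls could reflect either.

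For S3, the 4 arrays allow 8 sign patterns, too few for a share under 0.05. The reading reported, with array 2 turned, gave 505 genes at an unadjusted p under 0.05 and the highest of the others 575, so 2 of the 8 patterns gave as many. The higher one turns arrays 2 and 4 against arrays 1 and 3, which lines up their block gradients. With print blocks centred, the reading reported gave 644 genes and the highest of the others 352, so 1 of the 8 gave as many. That reading was itself set by the correlation of array 2 with the others (mean 0.0997). Its first rank is therefore largely built in and is no separate evidence of an effect on genes.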
